A study of Candida albicans with 9 samples.

How the data were processed

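RNA from 9 samples of *Candida albicans* was hybridised to one-colour (Cy3) Agilent arrays, 3 arrays each for unexposed cells, 15 min and 45 min with 3 µM FR59. Per the labels' protocols, total RNA was extracted with glass beads and labelled with an Agilent one-colour labelling kit. Per the file headers, spots were quantified with Agilent Feature Extraction 10.7.3.1, which subtracted background with spatial detrending and applied multiplicative detrending. The deposited scanner files give each spot's brightness as intensity on a linear scale, with no normalization between arrays. The value table that the authors deposited holds values on a log2 scale that are centred per probe across the samples. The table's log2 scale and direction were settled by setting its columns against the scanner values (slopes of 0.931 to 0.97 in 8 of 9 samples), while the exact scaling between arrays stays unknown. Its column medians lay between -0.0192 and 0.0168. In order of replicate number they were 0.0168, 0.0112 and 0.0121 in control, -0.0192, -0.0074 and -0.0081 at 15 min, and 0.0060, 0.0042 and 0.0055 at 45 min. It lists 12202 probes in 12203 lines, 1 probe being present in duplicate.

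For the main values, the log2 of the processed signal had each array's 75th percentile over the non-control spots subtracted. Spots flagged as non-uniform or population outliers were left out (9 to 65 per array), no spot was saturated, and control spots were left out. The 2 spots of each probe were averaged. A probe was kept where it was well above background on every array of at least 1 group, which left 11479 probes. The kept probes of a gene, 2 at most, were averaged, which gave 5786 genes. Across 5693 genes with 2 probes kept, the log2 changes of the probes correlated at r = 0.969 at 15 min and 0.969 at 45 min without 45 min replicate 1. A probe with at least 50 of 60 bases identical to a probe of another gene was found by blastn 2.17.0 for 105 tested genes. Such genes may share signal, and they made up 0, 5 and 3 of the genes called over all 9 arrays at 15 min, at 45 min and between the times (1, 8 and 9 without 45 min replicate 1).

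Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with all 9 arrays in 1 fit on group and Benjamini-Hochberg adjustment over all genes of a comparison. A gene was called changed at an adjusted p below 0.05 with a change of at least 2-fold (1 on the log2 scale). Groups came from the sample titles. The design text calls the experiments independent and nothing further says that the replicates came from separate cultures, so p-values measure the spread between these samples, part of which may be technical. On simulated data with 200 changed genes among 5786, true changes of 1.5, 2 and 3 on the log2 scale at 15 min were recovered for 42.4%, 83.6% and 89.6% of genes in the 9-array fit and for 98.5%, 98.5% and 100% without 45 min replicate 1. For 45 min the shares were 40.9%, 80.6% and 89.6%, and 98.5%, 98.5% and 100%. False calls in the 9-array fit were 6 at 15 min and 1 at 45 min, and 0 for each without 45 min replicate 1. The simulations spread the noise evenly over the arrays, while in the data 45 min replicate 1 stood far apart. The 9-array shares may therefore overstate recovery in these data. At 15 min that fit called 4 genes at least 4-fold higher, against 14 without 45 min replicate 1.

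Each array's slide was read from the scanner files. Slide 1 held the 3 control arrays and 15 min replicate 1, slide 2 held 15 min replicates 2 and 3 and 45 min replicate 2, and slide 3 held 45 min replicates 1 and 3. The slide of 45 min replicate 1 is that of its scanner file, which may not be the slide behind the authors' values. No arrays held identical signals.

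Before the data were examined, the comparisons, the tests, 31 gene lists, the rule for naming genes and most alternatives were fixed. The rule took called genes with a gene name by the size of their change, and called members of gene lists that passed. It also took ERG11, CDR1, CDR2, MDR1, FLU1, TAC1, MRR1, HSP90 and CAP1 whatever their values. Where only systematic identifiers are given, it took the 2 called genes that rose most and the 2 that fell most in each comparison with control. The array files hold 6089 identifiers of the orf19 kind and 12 beginning with CaalfMp. The gene table used (assembly ASM18296v3) lists 6263 genes by another kind of locus tag, and 0 of the orf19 identifiers matched it. The 31 gene lists were therefore not tested and no result is given by gene name. The genes fixed for naming could not be found among the identifiers and are not reported. The alternatives were quantile and median scaling, normexp background correction (offset 50), other filters on dim probes, the brightest probe per gene, the replicate number or the slide as a block, only the groups compared, array weights, the authors' value table, other thresholds and leaving out each array. Chosen after the data were seen were slide and replicate blocks without 45 min replicate 1, scaling on 10 spike-in probes, fits within slides and the split of the controls between the exposure times. Where a fit left a group with 1 array, that array was assumed to vary like those of the other groups.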

Results

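Gene expression was measured in the yeast *Candida albicans* before and after exposure to FR59, a compound that the labels call macrocyclic, at 3 µM. The design names the strain CAF2-1, a laboratory strain, while the source label of each sample calls it a clinical isolate. Cells growing in log phase in the rich medium YPD were harvested unexposed (control) or after 15 or 45 min with the compound. Each group had 3 one-colour arrays, described as independent experiments, so 9 arrays were available and their number limits the precision. The labels name 1 unexposed control group and no solvent-treated or time-matched control, so each exposure effect also holds any effect of the solvent and of the time in culture.

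Each array carried 24404 spots for transcripts, which represented 12202 probes of 60 bases and 6101 gene identifiers, of which 5786 were tested. In 8 of the arrays, between 93.8% and 95.03% of the spots were well above background, the median spot signal lay between 3135 and 5080 intensity units, and no spot was saturated. These 8 arrays correlated with each other at Pearson's r of 0.979 to 0.999 across genes, which are not independent replicates. The scanner file of 45 min replicate 1 stood apart. Its median signal was 1211 with 97.6% of spots well above background, and its r with the other arrays was 0.751 to 0.76. For 52.1% of the genes (3012 of 5786) it lay at least 2-fold from the mean of the other 45 min arrays, which lay that far from each other for 0.467% of the genes (27 genes). The authors' value table, which holds their processed values of the same samples, did not show this departure. In that table's column for the sample, deviations from the median of the other samples correlated with the scanner deviations at r = 0.036 across probes, against 0.977 to 0.989 for the other 8 samples. For those 8 samples too, the median left out 45 min replicate 1. The table's values are centred per probe, so r between its columns cannot be set against r between the scanner arrays. Its column for 45 min replicate 1 correlated with those for 45 min replicates 2 and 3 at r = 0.811 and 0.657. Replicates 2 and 3 correlated with each other at 0.632 there. The highest r of the replicate 1 column was -0.225 with control columns and -0.04 with 15 min columns. The counts of changed genes are therefore given over all 9 arrays, without that array, and from the authors' value table.

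**Figure D1:**
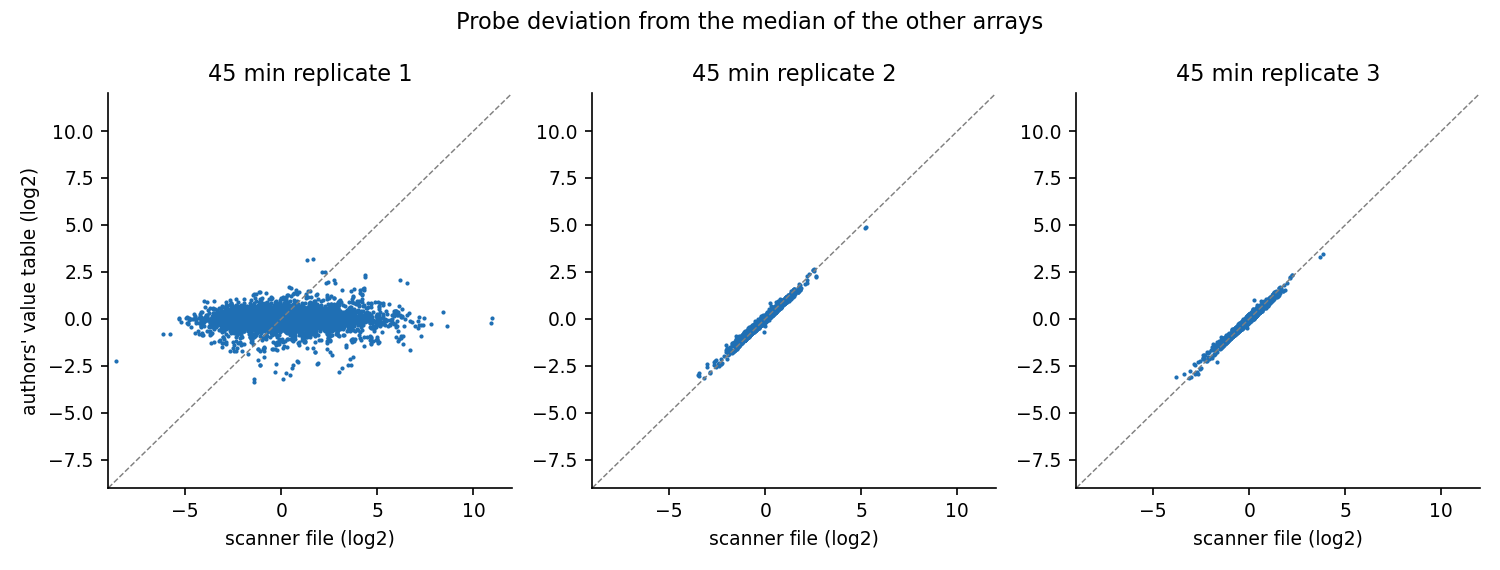
Deviation of each probe from the median of the other arrays (log2), from the scanner file on the x axis and from the authors' value table on the y axis, for the 3 samples exposed for 45 min, with 1 point per probe and the dashed line marking equal values. For each sample, 45 min replicate 1 was left out of that median. Replicates 2 and 3 follow the line (r = 0.983 and 0.98), and replicate 1 does not (r = 0.036).

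The first comparison set cells exposed for 15 min against unexposed cells. The array files pair their systematic identifiers with no gene name, and no name is assigned here, so the transcripts are given by identifier and probe sequence. The transcript orf19.5958 rose from a level of -3.14 ± 0.12 (SD, n = 3) in control to 3.08 ± 0.013 (SD, n = 3) at 15 min, in log2 units relative to the array's 75th percentile. This was a log2 change of 6.21 (SE 0.293), or 74.1-fold, with a limma adjusted p of 0.000154 (Benjamini-Hochberg). The transcript orf19.23 rose 22.6-fold (log2 4.501, SE 0.22, limma adjusted p 0.000154), from -3.81 ± 0.26 to 0.70 ± 0.073 (SD, n = 3 each). All 3 exposed arrays lay above all 3 control arrays for both transcripts.

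Both probes of each transcript moved alike. For orf19.5958, the probe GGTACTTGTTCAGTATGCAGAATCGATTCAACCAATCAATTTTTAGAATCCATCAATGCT changed by 6.31 and the probe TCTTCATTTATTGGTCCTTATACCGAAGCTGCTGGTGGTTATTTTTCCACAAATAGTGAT by 6.11 on the log2 scale. For orf19.23, the probe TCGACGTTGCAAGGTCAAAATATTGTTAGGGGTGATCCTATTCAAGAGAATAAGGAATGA changed by 4.42 and the probe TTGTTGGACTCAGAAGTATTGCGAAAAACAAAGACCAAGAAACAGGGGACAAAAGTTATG by 4.58. The longest match of these 4 probes to a probe of another gene covered 19 of 60 bases. Genome positions were not used here.

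Over all 9 arrays, 5 genes rose at 15 min, between 1.94 and 6.21 on the log2 scale, and 4 of them rose at least 4-fold. No gene fell by the limma test, with 242 genes lower at an unadjusted p under 0.05. Without 45 min replicate 1, which enters this comparison only through the shared estimate of spread, 59 genes changed, 49 higher and 10 lower. The 5 genes were all among them in the same direction. The median called rise was then 1.48 and the median called fall -1.07 on the log2 scale, and 14 genes rose at least 4-fold while no gene fell that far. With no minimum fold, 5 genes passed the limma test over all 9 arrays, all of them higher. Without 45 min replicate 1 that count was 2507 (979 higher, 1528 lower), and in the authors' value table it was 2598 (1141 higher, 1457 lower). The median log2 change over all genes was -0.086 (median SE 0.0821) and -0.056 (median SE 0.0772) in these fits. Small falls were therefore not told apart from a shift common to all genes. Slide was also not separated from exposure for changes under 2-fold in these counts. At the 2-fold minimum, the authors' value table gave 57 genes (51 higher, 6 lower), of which 54 were shared with the 59.

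The control arrays and 15 min replicate 1 shared a slide, and within that slide 101 genes changed (77 higher, 24 lower). With slide as a block, 2 genes were called over all 9 arrays and 103 without 45 min replicate 1. That block leaves the 15 min change to 15 min replicate 1 against the controls, as in the fit within the slide. The 9-array count was 3 without control replicate 3, 2 without 15 min replicate 2 and 3 without 15 min replicate 3. Scaling on spike-in probes, a choice made after the data were seen, ended all calls at 15 min (68 genes at an unadjusted p under 0.05). The limma adjusted p was then 0.063 for orf19.5958 and 0.11 for orf19.23, while their log2 changes were 6.19 and 4.48. The 75th percentile of 45 min replicate 1 lay 0.388 above its spike-in mean on the log2 scale, against 2.013 to 2.326 in the other arrays. That array enters this comparison only through the shared estimate of spread, and no count under this scaling is given without it.

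The second comparison set cells exposed for 45 min against the same unexposed cells. The transcripts orf19.5958 and orf19.23 had the largest rises here as well. Over all 9 arrays, orf19.5958 reached 3.42 ± 0.65 (SD, n = 3), a 94.1-fold rise (log2 6.56, SE 0.293, limma adjusted p 9.72e-05), and orf19.23 reached 0.98 ± 0.38 (SD, n = 3), a 27.5-fold rise (log2 4.78, SE 0.22, limma adjusted p 9.72e-05). The transcript orf19.1691 fell most, from -2.96 ± 0.97 in control to -6.36 ± 1.03 (SD, n = 3 each), which was 10.5-fold (log2 -3.39, SE 0.619, limma adjusted p 0.0475). The transcript orf19.7218 fell 4.65-fold, from -2.24 ± 0.20 to -4.45 ± 0.70 (SD, n = 3 each; log2 -2.22, SE 0.324, limma adjusted p 0.0211). For all 4 transcripts, the 3 exposed arrays lay on one side of the 3 control arrays.

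When 45 min replicate 1 was left out, the spread of the 45 min group narrowed and the changes were larger. The rise of orf19.5958 was then 121.8-fold (log2 6.93, SE 0.085, limma adjusted p 1.31e-10) and that of orf19.23 was 32.0-fold (log2 5.002, SE 0.131, limma adjusted p 4.18e-08). The fall of orf19.1691 was 15.7-fold (log2 -3.97, SE 0.465, limma adjusted p 0.000307) and that of orf19.7218 was 6.13-fold (log2 -2.62, SE 0.124, limma adjusted p 2.34e-06). The authors' value table gave log2 changes of 7.23, 5.10, -3.68 and -2.57 for these transcripts in the same order.

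The 2 probes of orf19.1691, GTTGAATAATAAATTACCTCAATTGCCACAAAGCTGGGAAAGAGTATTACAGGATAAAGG and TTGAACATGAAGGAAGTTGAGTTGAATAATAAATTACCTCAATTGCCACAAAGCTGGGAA, overlap in sequence and changed by -3.39 and -3.40 on the log2 scale. The probes of orf19.7218, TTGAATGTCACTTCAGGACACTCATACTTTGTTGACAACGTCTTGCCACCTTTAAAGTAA and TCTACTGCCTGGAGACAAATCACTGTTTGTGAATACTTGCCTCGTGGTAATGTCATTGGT, changed by -2.24 and -2.19. The longest match of these probes to a probe of another gene covered 30 of 60 bases.

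**Figure D2:**
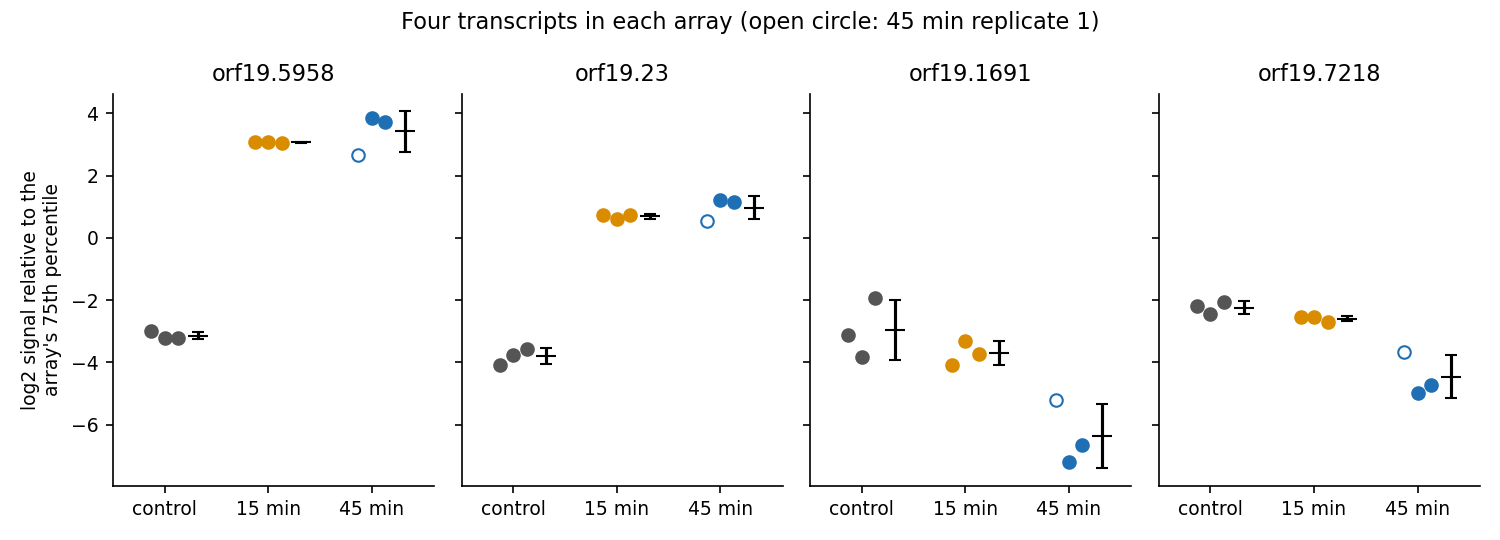
Level of each of the 4 transcripts in each array (y axis, log2 signal relative to the array's 75th percentile) in control cells and after 15 or 45 min with FR59; points are single arrays, bars beside them give the mean and SD of 3 arrays, and the open circle is 45 min replicate 1. For orf19.5958 the control arrays lie between -3.21 and -2.995 and the exposed arrays between 2.68 and 3.86.

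Over all 9 arrays, 61 genes changed at 45 min, 35 higher and 26 lower. Of these, 15 rose and 4 fell at least 4-fold, with a median called rise of 1.71 and a median called fall of -1.40 on the log2 scale. Leaving out 45 min replicate 1 gave 197 changed genes, 91 higher and 106 lower, of which 22 rose and 19 fell at least 4-fold. Of the 61 genes, 55 were called in the same direction among the 197. The authors' value table gave 190 genes (91 higher, 99 lower), and 173 of the 197 were shared with it. With no minimum fold, 82 genes passed the limma test over all 9 arrays (45 higher, 37 lower), 1782 without 45 min replicate 1 (871 higher, 911 lower) and 2461 in the authors' value table (1172 higher, 1289 lower). For changes under 2-fold in these counts, slide was not separated from exposure.

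The 9-array count moved when single arrays were left out. It was 7, 6 and 8 without control replicate 1, 2 or 3, and 36, 14 and 17 without 15 min replicate 1, 2 or 3. Without 45 min replicate 2 or 3 it was 27 or 51. Leaving out a 15 min array did not alter the log2 changes here, so those counts moved through the shared estimate of spread. The falls of orf19.1691 and orf19.7218 lost their call in each of these settings with 1 array left out, and the limma adjusted p ran from 0.0618 to 0.183. Their log2 changes in those settings were -3.83 to -2.87 and -2.33 to -1.96. Over 26 alternatives of all kinds, orf19.1691 lost its call in 15 and orf19.7218 in 12, with no change of direction. The limma adjusted p of orf19.1691 was 0.0583 with median scaling, 0.0752 with normexp and 0.0568 with no filter on dim probes, against 0.0475 in the main values and a range of 4.85e-05 to 1 over all alternatives. When only the groups compared were fitted it was 0.249, and that of orf19.7218 was 0.198. No slide held both control and 45 min arrays. A slide block therefore makes the 45 min change a sum of within-slide differences. These are 15 min replicate 1 against the controls, and 45 min replicate 2 against 15 min replicates 2 and 3. The arrays of slide 3 do not enter that sum. With slide as a block, 0 genes were called by limma over all 9 arrays (146 at an unadjusted p under 0.05) and 253 without 45 min replicate 1. The log2 changes of orf19.5958 and orf19.23 with that block were 6.99 and 5.08, with limma adjusted p 0.195 for each over all 9 arrays and 1.41e-05 and 0.001 without 45 min replicate 1. Those of orf19.1691 and orf19.7218 were -4.81 and -2.65, with limma adjusted p 1 for each, and 0.0205 and 0.0027 without that array. Spike-in scaling gave 16 genes, 11 higher and 5 lower. Under it the log2 changes were 5.925 for orf19.5958, 4.151 for orf19.23, -4.025 for orf19.1691 and -2.848 for orf19.7218, with limma adjusted p of 0.00897 to 0.0381.

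The third comparison set 45 min against 15 min of exposure, which tests directly whether the responses differed with time. The transcripts orf19.5958 and orf19.23 were not called between the times over all 9 arrays, with differences of log2 0.35 (SE 0.293, limma adjusted p 0.468) and 0.28 (SE 0.22, limma adjusted p 0.447). Without 45 min replicate 1 the differences were 0.72 (limma adjusted p 0.000488) and 0.50 (limma adjusted p 0.016). The authors' value table gave 0.95 (1.93-fold, limma adjusted p 4.7e-06) and 0.59 (limma adjusted p 0.00252). These differences passed the limma test but lay under the minimum of 2-fold. The transcript orf19.1691 stood at -3.71 ± 0.39 and orf19.7218 at -2.59 ± 0.087 (SD, n = 3 each) at 15 min, where neither was called against control over all 9 arrays (log2 -0.74 and -0.36, limma adjusted p 0.923 and 0.957). The limma adjusted p at 15 min was 0.169 and 0.03 without 45 min replicate 1 and 0.182 and 0.0394 in the authors' value table. Array weights called orf19.1691 lower at 15 min (log2 -1.34, limma adjusted p 0.00482), and over all alternatives its adjusted p ran from 0.00482 to 1. Those weights were 0.951, 1.14 and 9.13 for control replicates 1, 2 and 3, whose levels of orf19.1691 were -3.13, -3.84 and -1.92. Without control replicate 3 its 15 min log2 change was -0.22. The differences of orf19.1691 and orf19.7218 between 45 and 15 min were -2.65 (SE 0.619, limma adjusted p 0.113) and -1.86 (SE 0.324, limma adjusted p 0.0623) over all 9 arrays. Without 45 min replicate 1 both were lower at 45 than at 15 min, by 9.34-fold (log2 -3.22, SE 0.465, limma adjusted p 0.00115) and 4.78-fold (log2 -2.26, SE 0.124, limma adjusted p 1.32e-05).

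Over all 9 arrays, 23 genes differed between the times, 9 higher and 14 lower at 45 min (6 and 15 when arrays were scaled on the median). Leaving out 45 min replicate 1 gave 152 genes, 58 higher and 94 lower, and 19 of the 23 were called in the same direction. The authors' value table gave 140 genes (46 higher, 94 lower), of which 127 were shared with the 152. One slide held 15 min replicates 2 and 3 and 45 min replicate 2, and within it 148 genes differed (53 higher, 95 lower). With slide as a block, limma called 0 genes over all 9 arrays (151 at an unadjusted p under 0.05) and 139 without 45 min replicate 1. That block leaves the difference to 45 min replicate 2 against 15 min replicates 2 and 3, as in the fit within the slide. The 9-array count was 0 without any single control array, 15 min array or 45 min replicate 2 (499 to 1506 genes at an unadjusted p under 0.05), and 2 without 45 min replicate 3.

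The overlap of the exposure times was then described. Over all 9 arrays, the 5 genes that rose at 15 min were also called higher at 45 min, against 0.03 for independent lists of these sizes. Without 45 min replicate 1, 36 of the 49 genes that rose at 15 min also rose at 45 min (0.77 for independent lists), and 6 of the 10 genes that fell at 15 min also fell at 45 min (0.18 for independent lists). The authors' value table gave 36 of 51 and 5 of 6 (0.8 and 0.1 for independent lists). Simulated unchanged groups sharing the same controls gave 0 shared calls in each of 100 simulations, which sets no baseline, since unchanged genes seldom reach the thresholds for a call. With the controls split so that the comparisons shared none (1 control for one exposure time and the other 2 for the other, 6 arrangements, without 45 min replicate 1), 28 to 37 genes rose at both times and 1 to 6 fell at both. Independent lists of those sizes would share 0.6 to 0.99 and 0.041 to 0.35 genes. In these arrangements the log2 changes correlated at r = 0.418 to 0.495 across genes, with a covariance of 0.0713 to 0.0797. A difference between slides 1 and 2 would still be shared, since all controls lay on slide 1 and slide 2 held exposed arrays of both times.

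The time course without 45 min replicate 1 held 13 genes called higher at 15 min and not at 45 min, and the direct test found 6 of them lower at 45 than at 15 min. Of 55 genes called higher at 45 min and not at 15 min, 26 were higher at 45 than at 15 min by the direct test. Of 100 genes called lower at 45 min and not at 15 min, 66 were lower at 45 than at 15 min. The authors' value table gave 7 of 15, 25 of 55 and 63 of 94 for these classes in the same order. In the 9-array fit no gene was called higher at 15 min and not at 45 min, 4 of 30 genes called higher only at 45 min were higher than at 15 min, and 9 of 26 called lower only at 45 min were lower.

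Across the 5786 genes, which are not independent replicates, the log2 changes at 15 and 45 min correlated at r = 0.319 over all 9 arrays, with a covariance of 0.0768. Unchanged groups sharing the controls gave a mean r of 0.0971 (highest 0.145) and a mean covariance of 0.0063 in 100 simulations. In the fit without 45 min replicate 1, r was 0.518 and the covariance 0.0824, against 0.445 and 0.0062 in the simulations, whose highest r was 0.524. The authors' value table gave an r of 0.551 and a covariance of 0.0835, against 0.501 (highest 0.541) and 0.0052 in the simulations. In the same order, the covariance exceeded its simulated mean by 0.0705, 0.0763 and 0.0782.

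**Figure D3:**
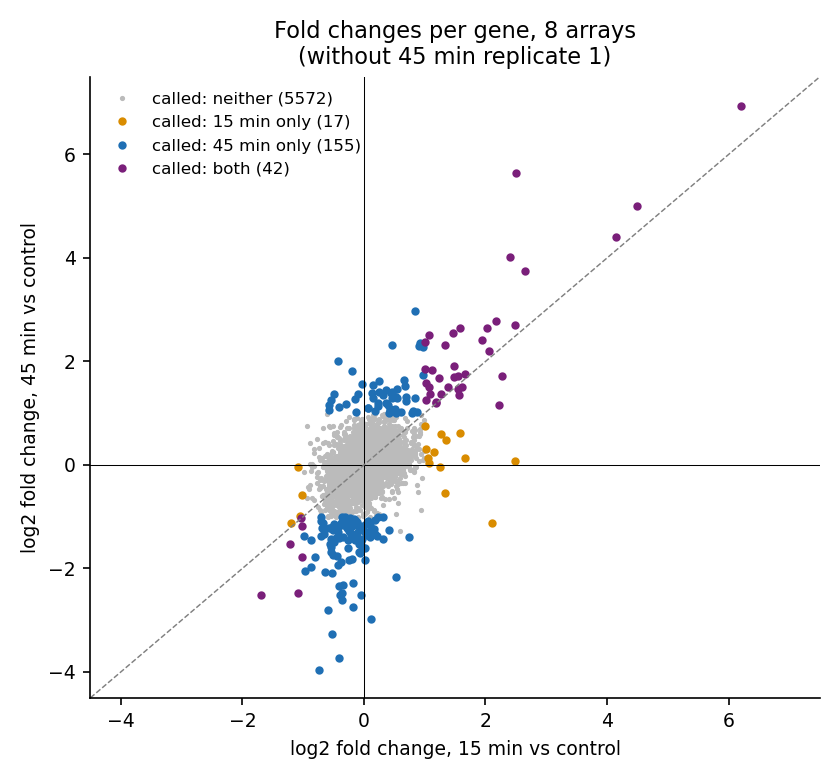
Log2 fold change against control after 15 min (x axis) and 45 min (y axis) for each of 5786 genes, computed without 45 min replicate 1; colours mark genes called at neither time, at 15 min only, at 45 min only or at both, and the dashed line marks equal changes. Of the called genes, 42 were called at both times, 17 at 15 min only and 155 at 45 min only.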

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

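The tests of the 45 min replicate 1 scanner file against the authors' value table were chosen after that comparison had been seen. The tests that kept reference arrays apart and the simulations of slide differences were added after the first slide tests. The other tests in this part were stated before their results were seen.

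The direct comparison of the exposure times stood out, with 23 genes called between 45 and 15 min over all 9 arrays and 152 without 45 min replicate 1. Splitting the 6 arrays of each comparison into groups of 3 in 10 ways gave as many called genes in 1 split, the real one, for each comparison. The real values were 5 genes at 15 min, 61 at 45 min and 23 between the times, and the highest of the other splits was 0 each time. With 10 splits the share cannot fall below 0.1.

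The scanner file of 45 min replicate 1 departed from the other 8 arrays by an SD of 1.73 on the log2 scale across genes, against 0.221 between the other 45 min arrays. A dim hybridisation would place the departure in dim probes, but among the brightest probes its SD was still 7.96 times that between the other 45 min arrays. RNA that mismatches single probes would move the 2 probes of a gene independently, but they moved together at r = 0.984 (0.981 for 3854 genes whose probes do not overlap). A response of this culture would appear in the authors' processed column too, and the correlation with it was 0.0362, if that column belongs to the sample. The same value is consistent with a scanner file of another hybridisation deposited under this sample, and which RNA it held stays open.

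For the genes called at 15 min from the slide 2 arrays against the slide 1 controls, a difference between slides was weighed against the exposure. On slide 1, which held the controls and 15 min replicate 1, the 56 genes had a median change of 1.42 in the called direction (quartiles 1.05 and 1.98), and all 56 (100%) changed in that direction. The calls and this test share the 3 controls, and 100 simulations in which slides alone made the difference gave medians of -0.0403 to 0.141 through that sharing. With each control in turn kept out of the calls and used alone as the reference, the medians were 1.53, 1.39 and 1.38, which argues against a slide difference for these sets. Exposure to FR59 for 15 min stays as a hypothesis, with solvent and time in culture untested.

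For the genes called between 45 min replicate 3 on slide 3 and the 15 min arrays, the same question arose. On slide 2, which held 45 min replicate 2 and 15 min replicates 2 and 3, the 171 genes had a median change of 1.09 in the called direction (quartiles 0.794 and 1.43), and 168 of 171 (98.25%) moved in that direction. The calls and this test share 15 min replicates 2 and 3, and 100 simulations in which slides alone made the difference gave medians of -0.0249 to 0.0838. With 15 min replicate 2 or 3 kept out of the calls and used alone as the reference, the medians were 1.06 and 0.983, which argues against a slide difference for these sets. Longer exposure is a candidate explanation, and longer time in culture was not separated from it.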

How the results depend on the processing

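The blocks without 45 min replicate 1, spike-in scaling and the fits within slides were chosen after the data were seen. Counts are given for 15 min against control, 45 min against control and 45 against 15 min, over main values of 5, 61 and 23. The correlation of the log2 changes (main value 0.319) is called r. Unless stated, the cause of a shift was not tested.

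Leaving out 1 array at a time gave 2 to 59, 6 to 197 and 0 to 152 genes and an r of 0.203 to 0.518, the upper ends coming without 45 min replicate 1. Array weights, which gave that array a weight of 0.00727 and control replicate 3 the highest, 9.13, gave 56, 214 and 143 genes (r 0.554). The authors' value table gave 57, 190 and 140 (r 0.551). Fitting only the groups compared gave 59, 4 and 0 (514 genes at an unadjusted limma p under 0.05 for the last). Quantile scaling gave 12 for the last. An adjusted p below 0.01 gave 6 genes at 45 min and 0 between the times (965 at an unadjusted p under 0.05).

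A replicate block gave 2, 7 and 0 (770 genes at an unadjusted p under 0.05 for the last; limma adjusted p 0.129 for orf19.1691 and 0.0733 for orf19.7218 at 45 min), and 59, 202 and 138 without 45 min replicate 1 (r 0.544). Whether the replicate numbers pair the samples was not settled. The correlations of same-numbered arrays ran from -0.135 to 0.0623 (-0.119 to 0.387 in the authors' value table). The scanner values of the 45 min group hold the departing file of replicate 1, so pairs with that group cannot decide. Control and 15 min arrays correlated at -0.135, 0.0437 and -0.0106 in order of replicate number. In the authors' value table the highest values were 0.387 (15 and 45 min, replicate 3) and 0.322 (control and 45 min, replicate 1). With slide as a block, the 45 min change is the sum of the 15 min change and the difference between the times. Its r therefore sets a part against the whole and does not show closer agreement of the times. A slide block gave 2, 0 and 0 (r 0.692), and 103, 253 and 139 without 45 min replicate 1 (r 0.692). Fits within slides gave 101 genes at 15 min and 148 between the times.

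Spike-in scaling gave 0, 16 and 0 (68 and 348 at an unadjusted p under 0.05 where 0) and moved the log2 changes of all genes by -0.025, -0.63 and -0.61 at the median (-0.025, -0.062 and -0.038 without 45 min replicate 1). Under it the differences between 45 and 15 min turned to -0.26 for orf19.5958 and -0.32 for orf19.23 (limma adjusted p 0.797 and 0.709). No other value of the 4 transcripts changed direction. Counting each transcript, comparison and alternative once, 274 values stayed on the same side of the threshold, 31 lost their call and 13 gained one. Counts stayed within 1.5 times the main count, or r within 0.208 (the SD of r over the 9 pairs of a 15 and a 45 min array), in 47 cases and not in 55. Over the alternatives the limma adjusted p of orf19.5958 ran from 1.37e-14 to 0.0633 at 15 min and from 1.9e-13 to 0.195 at 45 min, and that of orf19.23 from 5.33e-11 to 0.11 and from 8.98e-10 to 0.195. The set tests of gene lists, with their alternatives, were not run, because no identifier matched a gene name. Probes without a group in which every array was well above background were left out, except where no filter on dim probes was applied.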

Other observations

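The test of consecutive identifiers and the set of identifiers beginning with CaalfMp were chosen after their values had been seen.

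Among the 197 genes called at 45 min without 45 min replicate 1, 9 pairs had consecutive orf19 numbers and changed in the same direction. Random sets of the same sizes gave a mean of 2.52 pairs, with a 95th percentile of 5 and a highest value of 10 in 10000 sets (one-sided permutation p 0.0014). Over all 9 arrays there were 2 such pairs against a random mean of 0.228 (one-sided permutation p 0.023). None of the 9 pairs shared a probe match of 40 bases or more, so the values do not point to signal shared between similar probes. That genes with consecutive identifiers respond together is a hypothesis prompted by these 9 pairs, which therefore cannot test it. Across 4134 consecutive pairs the log2 changes correlated at r = 0.0904. Whether consecutive numbers mark neighbouring genes was not tested, because the identifiers carry no position here.

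In the scanner file of 45 min replicate 1, the 7 tested identifiers beginning with CaalfMp had a mean level of -3.42 on the log2 scale relative to the array's 75th percentile. In the other 8 arrays that mean lay between -7.51 and -6.90. The rise over the mean of the other 45 min arrays had a median of 4.23 (from 1.55 to 6.21), at the 98.02th percentile of 10000 random lists of the same size matched on mean expression. The 75th percentile lay 0.388 above the spike-in mean in this array, against 2.013 to 2.326 in the other 8. Relative to the spike-in probes the rise would therefore be smaller. In the same file orf19.5958 stood at 2.68 and orf19.23 at 0.54, above all control arrays.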
